A study of Mus musculus with 6 samples.

How the data were processed

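RNA of 6 samples of mouse sarcoma cells was measured on 3′ expression arrays of Affymetrix, 3 samples heterozygous and 3 null for Dicer. Per the labels' protocols, cells were harvested at confluence, and RNA was extracted with Trizol, treated with DNase, purified on columns and labelled with biotin as cRNA. The authors' deposited table holds log2 values per probe set, read as log2 because GCRMA writes that scale and the range of 0.40 to 14.18 fits it. Per the submitters' processing notes, R 2.11.1 and GCRMA 2.20.0 were used, a method that corrects background by probe sequence, normalizes quantiles between arrays and summarises probes into probe sets. Its settings, the chip definition file and any filter are not given in the sources used here. Because GCRMA sets unexpressed probe sets to low values with little spread, differences that start below a log2 value of about 3 depend on that background model. Quantile normalization also removes any overall shift in RNA amount between groups. The arrays' medians lay between 3.32 and 3.43.

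Samples were grouped by the genotype in their titles. The groups share replicate numbers, and whether these pair the samples was checked through the correlation of deviations from the group means. Nothing in the labels gives a batch or a scan date. No 2 arrays held identical values. Correlations were 0.935 to 0.973 within heterozygous arrays, 0.972 to 0.979 within null arrays and 0.910 to 0.955 between the groups. Signal over background, not read depth, sets what such arrays can show: of 81 probe sets for olfactory, vomeronasal and trace amine receptors, 78 had a mean under 3, and that value was the minimum mean over the 6 arrays for testing, which left out 20652 probe sets.

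Probe sets were named through the platform annotation given for this work. It ties 34945 of them to 1 gene symbol, 932 to several and 9160 to none, and names were taken only from the first kind. Of these, 34741 matched the GRCm38.p6 gene table by Entrez ID, which changed 0 symbols. No coordinates were used, since the arrays' files name no build. A gene was represented by its tested probe set with the highest mean.

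The comparison used limma 3.58.1 in R 4.3.3, with a linear model per probe set and moderated statistics (lmFit and eBayes), no block, two-sided, and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. Lists of genes written from general knowledge before the data were examined (33 of them: targets of 5 microRNAs or clusters, pathways, and markers of other cell types) were tested with limma's camera, with a preset correlation of 0.01 and, as an alternative, an estimated one, and with fry. Adjustment was over the 30 lists with at least 5 tested members. Camera was also run over the genes of each chromosome. None of the lists was chosen on these samples. The series title, known when they were written, names let-7 and Nr6a1, and the let-7 and oncofetal lists hold Nr6a1. Its rise is therefore not independent support for those lists.

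The genes named in the text followed a rule fixed before the data were examined. It took Dicer1, Nr6a1, Hmga2, Lin28b and Igf2bp1 to Igf2bp3, the 12 highest and 12 lowest changed genes whose groups did not overlap, up to 4 called members of each list or else the member with the smallest p, and up to 3 called genes of a called chromosome, with Riken and predicted genes skipped. Of the smallest-p members of lists without a call, the text gives Cdc6, Pdgfra, Hoxa9 and Xist and leaves out the others. Genes outside the rule are named only as the remaining called members of a list or in the closing section.

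On simulated data of 24385 probe sets with 200 changed, limma recovered 5.97% of 2-fold, 44.8% of 4-fold and 81.8% of 16-fold changes, with 1 false call among 89, and made 0 calls where nothing was changed. In the real data 756 probe sets were called, more than the simulation changed, so these rates need not hold there. The simulated noise was also normal and independent between probe sets. Real genes can move together across arrays, as the proliferation list did (estimated correlation 0.727). The simulation therefore does not give the rate of false calls for such data. Alternatives were another or no minimum, trend and robust moderation, quantile normalization again, centred arrays, ordinary t statistics, array weights, the replicate number as a block, a 2-fold minimum, other choices of probe set per gene, and each array left out in turn. A planned test of microRNA seed matches needs 3′ UTR sequence and was not run, because no genome was used here. Figures were drawn with matplotlib 3.10.9.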

Results

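The arrays measured messenger RNA in mouse sarcoma cell lines of strain C57BL6/J. In 3 samples 1 copy of Dicer1 was intact (Dicer heterozygous) and in 3 samples none was (Dicer null). Dicer is the ribonuclease that cuts microRNA precursors to their mature form, and let-7, which the title of the series names, is a microRNA family of differentiated cells. The only comparison that the design implies is Dicer null against Dicer heterozygous, and it asks which transcripts differ when Dicer is missing. Each array held 45037 probe sets as log2 GCRMA values between 0.40 and 14.18, and 24385 of them, standing for 11425 named genes, had a mean of at least 3 and were tested. The number of arrays, 3 per group, limits the precision. The design text speaks of lines and the titles of replicates, and nothing says that the 3 samples of a group were grown as separate lines or cultures, so the p-values measure the spread between these samples only.

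Between the groups 395 genes changed, 166 of them higher and 229 lower in the Dicer null arrays. Among the 12 highest log2 differences, in no order, were those of Car8, a carbonic anhydrase relative, at least 68.6-fold higher, St8sia1, which makes the ganglioside GD3, at least 41.5-fold higher (95 without null replicate 1, 24.4 without null replicate 2), and Hmgcll1, related to the lyase of ketone body synthesis, at least 34.1-fold higher. Otor, the LIM homeobox gene Isl1, the cholesterol transporter Abcg1, the RNA-binding protein Igf2bp1, the imprinted noncoding RNA Kcnq1ot1, the serine protease Fap, Arhgap6, Nol4l and Clec1a were the other 9. The lowest were Pdk4, a kinase that inhibits pyruvate dehydrogenase, at least 239-fold lower (log2 value 10.9 ± 0.76 against 2.45 ± 0.48, SD, n = 3 each), and Cd200, a membrane glycoprotein that restrains myeloid cells, at least 136-fold lower. Emx2, Acta2, Gnao1, Sulf1, Cd109, Itih2, Col11a1, Tmem98, B3galt1 and Zfp503 were the other 10 at that end. A fold written as "at least" sets the brighter group against a log2 value of 3, because the dimmer group lay below it. With such folds in place of log2 differences Kcnq1ot1, Col11a1 and Zfp503 would not be among these 24 genes.

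In limma's moderated test with Benjamini-Hochberg adjustment, 756 probe sets changed, 394 higher and 362 lower, and 5660 had an unadjusted p under 0.05. Among the changed genes 372 differed at least 2-fold (154 higher, 218 lower), and 34 rose and 75 fell at least 8-fold. In 395 of the 395 the 3 values of one group all lay above the 3 of the other, which a call at this threshold all but requires. Among all tested genes such a separation held for 32.2%, and by chance it holds for 10% with 3 against 3. Of the changed genes 176 had another tested probe set. In 89 of these another probe set was called with the same sign. In 10 another probe set had the opposite sign, and in 2 it was also called. The count of 395 fell to 65 without heterozygous replicate 2, 105 without null replicate 1, 29 without null replicate 2 and 36 without null replicate 3. It was 0 with ordinary t statistics in place of limma's moderated ones, with 2442 genes at an unadjusted p under 0.05 there, and 3333 or 1496 with array weights, by the default and the gene-by-gene method. Of the 45 changed genes that the naming rule picked, 35 stayed called without heterozygous replicate 3 but 15 without null replicate 2.

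**Figure D1:**
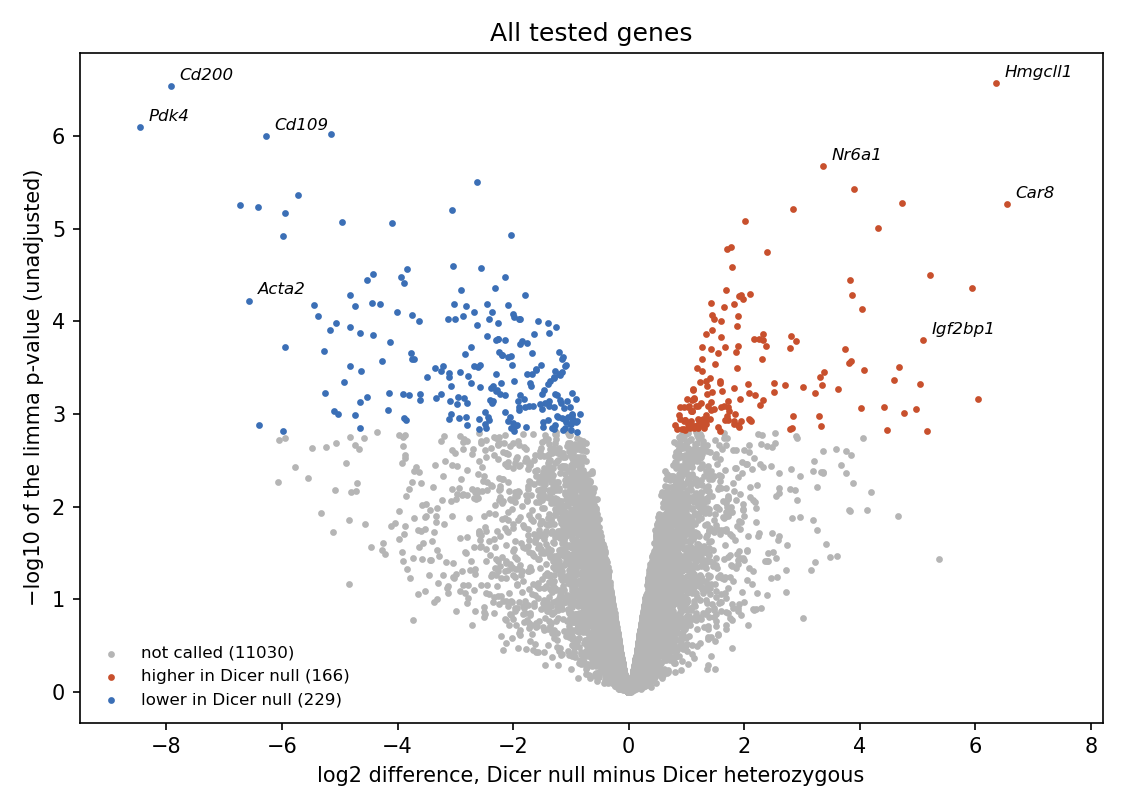
Each point is 1 tested gene, with the log2 difference (Dicer null minus Dicer heterozygous) on the x axis and −log10 of limma's unadjusted p-value on the y axis. The 166 genes higher in the Dicer null arrays (red) and the 229 lower (blue) passed an adjusted p of 0.05, and 11030 genes (grey) did not.

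The targeted gene, Dicer1, did not differ. Its probe sets gave 8.32 ± 0.24 against 8.46 ± 0.09 and 8.12 ± 0.43 against 8.39 ± 0.21 in heterozygous and null arrays (SD, n = 3; limma adjusted p = 0.693 and 0.573). The labels do not say which part of the gene was deleted, and a probe set outside that part checks nothing, so these values neither bear out nor question the labels. Nr6a1, the orphan nuclear receptor in the series title, rose 10.3-fold, from 6.83 ± 0.31 to 10.2 ± 0.07 (SD, n = 3; log2 difference 3.37, SE 0.20, limma adjusted p = 0.00647). Its 4 tested probe sets were all higher in null arrays, and 3 of them passed. The values above are those of the brightest, and the others gave log2 differences of 3.29, 2.72 and 1.18.

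Of 46 tested members of the let-7 target list, 10 rose and 0 fell, and 14 rose when adjusted over the list alone. Nr6a1, which the series title names, is among those that rose. Besides Nr6a1, the RNA-binding proteins Igf2bp1 (log2 difference 5.10, SE 0.63) and Igf2bp3 (2.09, SE 0.33), which are abundant in embryos, rose in each of their 4 and 6 tested probe sets. Trim71, a regulator of early development, rose by 2.89 (SE 0.36) and the nuclease and helicase Dna2 by 2.84 (SE 0.49). Arid3a, Arid3b, Hic2, Map3k1 and Prtg were the other called members. As a fold, the rise of Igf2bp1 was 34.3, but 21.8 without heterozygous replicate 2 and 54.5 without heterozygous replicate 3. These folds are those of its brightest probe set. Its other tested probe sets gave smaller log2 differences, 3.71, 4.17 and 3.63 (SE 0.35, 0.33 and 0.24). Hmga2, a chromatin protein and let-7 target, stood at 12.2 ± 0.24 in heterozygous and 12.7 ± 0.04 in null arrays (SD, n = 3; limma adjusted p = 0.182) and was not called. In each of its tested probe sets the null arrays all lay above the heterozygous ones, but none was called. Lin28b, which blocks let-7 maturation, lay at background in both groups (1.23 and 1.45) and was not tested, and Igf2bp2 was not analysed here. The list's median log2 difference was 0.47, with 41 of 46 members above 0, and limma's camera gave an adjusted p of 1.48e-08. The adjusted p = 0.0509 with an estimated correlation does not pass. With fry, which asks only whether the members move one way, the adjusted p was 0.000233.

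**Figure D2:**
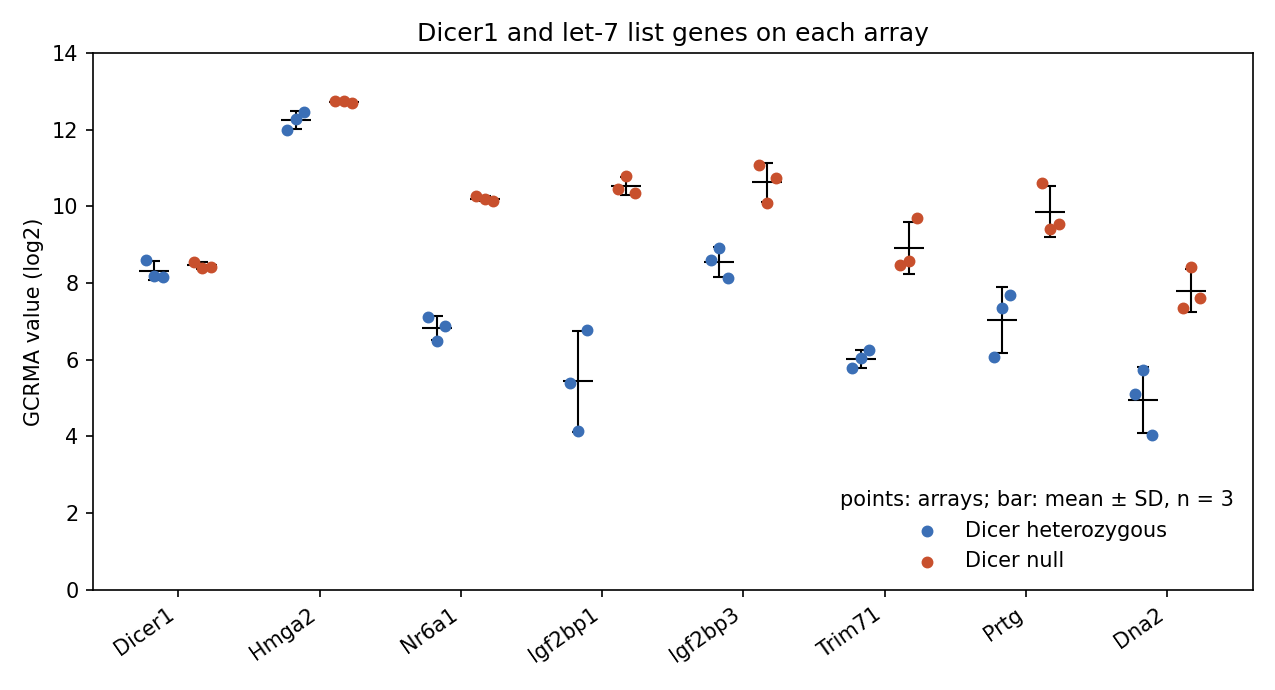
The y axis gives the log2 GCRMA value on each array for Dicer1 and 7 genes of the let-7 target list, with points for arrays and bars for the mean ± SD of 3 arrays. Dicer1 overlaps between the groups. Values in the null arrays all lie above those in the heterozygous arrays for Hmga2, Nr6a1, Igf2bp1, Igf2bp3, Trim71, Prtg and Dna2. Hmga2 differs by 0.48.

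The oncofetal list, genes active in embryos and again in tumours, had 6 of 17 tested members higher and 0 lower, 6 also when adjusted over the list alone. The 6 were Igf2bp1, Nr6a1, Trim71, Prtg, Igf2bp3 and Arid3a, all of which the let-7 list holds too. The median log2 difference was 1.77 (camera adjusted p = 0.000187 in limma; adjusted p = 0.149 with an estimated correlation; fry adjusted p = 0.000160). Over all 24 members, dim ones included, the median was 0.24 (camera adjusted p = 0.000480), and over the 17 it was 1.07 with array weights and 0.84 with the proliferation list's median per array as a covariate (0.00233). Without the members shared with the let-7 list the median was -0.28 and limma's adjusted p 0.776.

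Proliferation genes were higher as a group only by camera with its preset correlation, and none was called singly. All 39 tested members had positive differences, with a median of 0.76, but 0 were called by limma over all probe sets or adjusted over the list alone. The nearest, the replication licensing factor Cdc6, stood at 7.64 ± 0.29 against 8.94 ± 0.39 (SD, n = 3; limma adjusted p = 0.057). The camera test gave an adjusted p of 7.70e-08 (limma), and the adjusted p = 0.907 with an estimated correlation, the members' estimated correlation being 0.727. With fry the list did not pass (adjusted p = 0.319). Heterozygous replicate 3 stood apart from the rest: the median of the list relative to each gene's mean was -1.08 there, against 0.03 and 0.00 in the other heterozygous arrays and 0.22, 0.61 and 0.17 in the null arrays. Without that array the median difference was 0.38 and the camera adjusted p 2.89e-05 in limma, and the list stayed called without any other array. With array weights the median was 0.38 by the default and 0.46 by the gene-by-gene method.

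**Figure D3:**
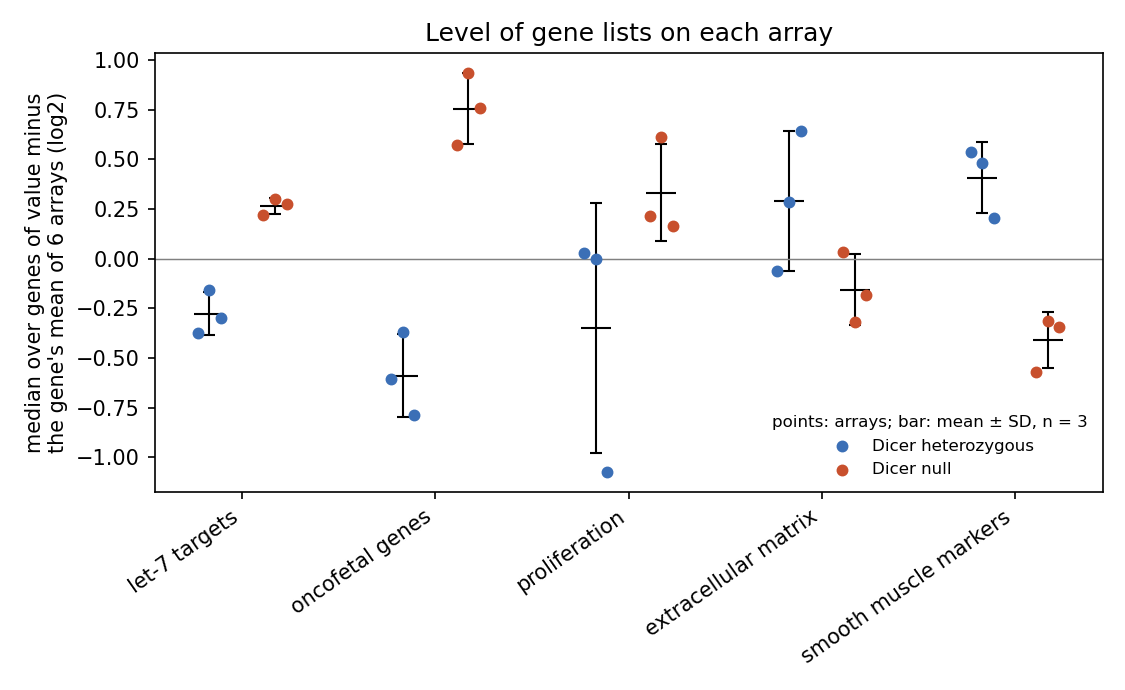
The y axis gives, for 5 gene lists, the median over the list's tested genes of the log2 value minus that gene's mean of 6 arrays, with points for arrays and bars for the mean ± SD of 3 arrays. The let-7, oncofetal, proliferation and smooth muscle lists separate the groups, extracellular matrix does not, and heterozygous replicate 3 lies at -1.08 for proliferation and at 0.64 for extracellular matrix.

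Several genes of the extracellular matrix and of contractile cells fell. Of 39 tested matrix genes 6 fell and 0 rose: Col11a1, a fibrillar collagen, by at least 25.9-fold, Mfap5, a microfibril protein, by at least 15.1-fold, Mgp, an inhibitor of calcification, 23.2-fold, Fbln5 22.9-fold, Timp3 6.96-fold and Fbln2 4.12-fold. Adjusted over the list alone 6 fell and 1 rose. Of 11 smooth muscle markers 2 fell, also when adjusted over the list alone: Acta2, smooth muscle actin, by 6.56 (SE 0.69) and Tagln, transgelin, by 5.27 (SE 0.69) on the log2 scale. Without 1 array several of these folds moved: Col11a1 to 65.6 and 13.2 (without heterozygous replicates 1 and 3), Mfap5 to 29.0 and 8.06 (heterozygous 2 and 3), Fbln5 to 14.4 (null 2), Acta2 from 94.6 to 160 and 58.5 (null 1 and 3) and Tagln from 38.6 to 25 and 64.5 (heterozygous 1 and 2). The other tested probe set of Acta2 differed by 0.50 (limma adjusted p = 0.293). Neither list passed with camera (in limma, adjusted p = 0.143 and 0.0945), while with fry the smooth muscle list did (adjusted p = 0.0371) and the matrix list did not (0.319). With an estimated correlation camera gave 0.590 for smooth muscle and 0.907 for matrix. With the preset correlation the matrix list passed without heterozygous replicate 1 (0.00287) or null replicate 1 (0.0331), and the smooth muscle list without heterozygous replicate 1 (0.0313), heterozygous replicate 2 (0.0438) or null replicate 1 (0.0425). In the Wnt list Ccn5 and the antagonist Dkk2 fell, 2 of 22, and among fibroblast markers Mfap5 and Fbln2 fell while Fap rose, 3 of 16. Igfbp6, which binds insulin-like growth factors, fell 17.1-fold, the single called gene of 25 in its list. Adjusted over that list alone, 3 members rose and 1 fell, and 16 of the 25 had positive differences. Heterozygous replicate 3 had the highest matrix level, 0.64, and heterozygous replicate 1 the lowest of its group, -0.06.

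Lists of targets of other microRNAs showed few calls. Tet3 rose 2.42-fold in the miR-29 list (25 tested), the apoptosis gene Bcl2l11 rose 3.30-fold in the list for the miR-17 cluster (25 tested), and in the miR-21 list Skp2 rose 2.77-fold and Timp3 fell (18 tested). None of 23 genes in the miR-34 list was called by limma, and Pdgfra came nearest (adjusted p = 0.0593). Adjusted over the list alone, 1, 4, 6 and 3 members rose and 0, 0, 1 and 3 fell in these 4 lists. The camera adjusted p values in limma were 0.208, 0.211, 0.165 and 0.924. In the microRNA pathway list the helicase Mov10 rose 3.19-fold, 1 of 20 (camera adjusted p in limma 0.165). Adjusted over that list alone, 5 members rose and 1 fell.

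The remaining tested lists did not pass as sets, with fry or with camera (camera in limma, adjusted p in brackets). They were imprinted growth genes (0.393), Hox genes (0.227), embryonic transcription factors (0.625, with Isl1 the 1 called of 29), p53 targets (0.972), interferon response (0.630) and cytokines (0.389). The TGF-beta response gave 0.503, the Wnt list 0.393, insulin-like growth factor and Ras signalling 0.208, glycolysis and hypoxia 0.165, and oxidative phosphorylation 0.515. Sterol synthesis gave 0.503, the ER stress list 0.776, and lysosome and autophagy 0.668. Markers of other cell types gave 0.924 for skeletal muscle, 0.671 for fibroblasts, 0.208 for cartilage and bone, 0.776 for adipocytes, 0.165 for epithelium, where Ocln rose, and 0.625 for neural cells. Without heterozygous replicate 1 the Wnt (0.0313) and epithelial (0.00558) lists passed, and without heterozygous replicate 2 that of glycolysis and hypoxia (0.0332). Endothelial and leukocyte markers had 3 tested genes each, too few for a set test, and none of them was called. The p53 list had a median of 0.02 and a mean of -0.12, and the test pointed down. The miR-34 list had a median of 0.01 and a mean of -0.08, and the test pointed up. The adipocyte list had a median of 0.24 and a mean of -0.13, and the skeletal muscle list a median of 0.02 and a mean of -0.07, with both tests pointing up.

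Of the 20 chromosomes tested, 2 shifted as a set, with genes assigned through the GRCm38.p6 gene table. The 645 genes of chromosome 8 had a median log2 difference of 0.19 and the 566 of chromosome 6 one of 0.16 (camera in limma, adjusted p = 0.00133 and 0.0143; adjusted p = 0.980 for both with an estimated correlation). On chromosome 8 10 genes were called higher and 6 lower, and on chromosome 6 13 and 11. Not every null array carried the shift, by the median relative to each gene's mean and to all tested genes. For chromosome 8 it was 0.19, -0.03 and 0.15 in null replicates 1, 2 and 3, and -0.09, -0.05 and -0.14 in the heterozygous ones. For chromosome 6 it was -0.04, 0.15 and 0.16 in the null replicates, and -0.14, -0.14 and 0.05 in the heterozygous ones. Of the called genes with the largest differences there, Gnao1, Slc7a2 and Pdgfrl on chromosome 8 fell, and on chromosome 6 Pdk4 and Mfap5 fell while St8sia1 rose. Without heterozygous replicate 3 the median of chromosome 8 was 0.125. Chromosome 6 was not called without heterozygous replicate 1 (0.102), heterozygous replicate 2 (0.0529) or null replicate 3 (0.187). Chromosomes 2 and 9 gave 0.0537 each and chromosome 7 gave 0.129, and in some fits without 1 array they passed. Xist, the RNA that coats the inactive X chromosome, stood at 11.34, 11.33 and 11.39 in the heterozygous arrays and at 9.82, 11.33 and 1.71 in null replicates 1, 2 and 3. The 9 probe sets of Y-linked genes lay between 0.73 and 1.96 in all 6 arrays.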

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

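Settings added to the plan after the data were seen were the floor at 3, gene-by-gene array weights, lists without shared members, probe sets without the s or x suffix alone, and the proliferation covariate. The other settings in these paragraphs were planned. Where no cause is given, the cause was not tested. In limma, 395 genes and 756 probe sets changed. Other minimums, no filter, trend and robust moderation, quantile normalization, centring, a 2-fold minimum, the floor and other probe set choices gave 316 to 526 genes. Ordinary t statistics gave 0 probe sets and 0 genes in limma's model (4873 and 2442 at an unadjusted p under 0.05), where Nr6a1, whose difference of 3.37 this setting cannot change, had an adjusted p of 0.0657. Array weights gave 6875 probe sets and 3333 genes by limma's default method, which warned that it had not converged. The gene-by-gene method, added after that count was seen, gave 2949 and 1496. Without 1 array, 44 to 857 probe sets and 29 to 463 genes changed. Nr6a1 was called in every alternative except ordinary t, with differences of 3.20 to 3.51 in the leave-one-out fits, and Dicer1 in none.

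The deviations of same-numbered arrays correlated at -0.06, 0.11 and 0.24, and 3 of 6 arrays correlated best with their own number. With 3 arrays per group these values cannot exclude that the numbers pair the samples. With the number as a replicate block, 116 probe sets and 73 genes were called (60 of them among the 395), and Nr6a1 had a limma adjusted p of 0.0484.

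An estimated correlation ended the camera calls of the let-7 (adjusted p 0.0509 in limma), oncofetal (0.149) and proliferation (0.907) lists and of chromosomes 6 and 8 (0.980 each). For the let-7 list the estimate, -0.01, lies below the preset 0.01, and the loss comes from the few degrees of freedom that this form of the test uses. In all other alternatives run on it the let-7 list stayed called, 5.44e-09 to 4.50e-06 without 1 array. The oncofetal list gave 0.776 without members of the let-7 list. The proliferation list gave 0.357 with its own median as a covariate, which its construction explains. Chromosome 6 ranged from 0.000367 to 0.187 without 1 array and chromosome 8 from 6.30e-07 to 0.0248. Of 480 values of the 27 uncalled lists, 13 became called: those the text gives without 1 array, smooth muscle with no filter (0.0259), trend and robust moderation (0.0460) and the mean of probe sets (0.0455), and with the proliferation covariate miR-21 (0.0348) and Hox (0.0158). Of 126 values of the 18 uncalled chromosomes, 10 became called and 18 changed sign. Chromosomes 2 and 9 passed without heterozygous replicate 1 (0.0463 each), heterozygous replicate 2 (0.0224 each), null replicate 1 (0.0213 and 0.00625) and null replicate 2 (0.0289 each), and chromosome 7 without heterozygous replicate 3 (0.0134) and null replicate 2 (0.0383).

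Acta2 turned from a fall of 6.56 to 0.50 (limma adjusted p 0.293) where a probe set without the s or x suffix was preferred, because another probe set then stands for it. The other sign changes were 34 values of uncalled lists, and the 18 of uncalled chromosomes, none of them called then by limma's camera (adjusted p in brackets). With no filter these were embryonic transcription factors and adipocyte markers (0.983 each). The p53 list changed sign with a minimum of 5 (0.997), centring (0.981), the replicate block (0.965) and the mean of probe sets (0.980), the last with skeletal muscle (0.980). Array weights turned miR-34, interferon and ER stress lists (0.876 each by default, 0.925 each gene-by-gene), and probe sets without suffix the miR-34 list (0.984). The proliferation covariate turned embryonic transcription factors (0.893), extracellular matrix, TGF-beta and Wnt (0.792 each), interferon (0.357), cytokines (0.752), skeletal muscle (0.493), fibroblast (0.987) and ER stress (0.577). Without 1 array the lists that changed sign ranged as follows: miR-34 0.636 to 0.971, p53 0.734 to 0.998, interferon 0.394 to 0.882, skeletal muscle 0.446 to 0.990, adipocyte 0.468 to 0.942, neural 0.623 to 0.917 and ER stress 0.508 to 0.968. The chromosomes that did so ranged likewise: chromosome 1 0.657 to 0.970, chromosome 3 0.540 to 0.938, chromosome 4 0.50 to 0.915, chromosome 5 0.503 to 0.938, chromosome 11 0.528 to 0.970, chromosome 12 0.528 to 0.970, chromosome 13 0.227 to 0.971, chromosome 16 0.544 to 0.938, chromosome 17 0.301 to 0.915 and chromosome 18 0.514 to 0.970.

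The seed family tests and their alternatives were not run, since no 3′ UTR sequence was used here. Signal near background limits folds: 25 of the higher and 47 of the lower changed genes had their dimmer group under a log2 value of 3.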

Other observations

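Kcnq1ot1, the noncoding RNA of an imprinted domain, was higher in null arrays in all 4 of its tested probe sets, at least 20.5-fold in the brightest (limma adjusted p = 0.0320). With 1 array left out that probe set stayed called only without heterozygous replicate 1. Cdkn1c, a protein-coding gene of the same domain, stood at 4.13 ± 1.25 against 5.60 ± 1.25 (SD, n = 3; limma adjusted p = 0.338), so no difference was detected there. Kcnq1ot1 fell under the naming rule, and Cdkn1c was chosen after its values were seen. Among 7 tested genes of the Hox A cluster 7 had higher values in null arrays, with a median log2 difference of 1.07, while in the Hox C cluster 2 of 7 did, with a median of -0.56, and in Hox D 4 of 6. None was called over all probe sets by limma. Adjusted over the list alone, 2 of the Hox A genes were called, Hoxa9 and Hoxa3. The difference between the clusters was noticed in the data and was not tested. Gata4, a transcription factor of heart and gonad development, stood at 2.09 ± 0.11 against 6.21 ± 2.47 (SD, n = 3; limma adjusted p = 0.106).

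Among the tests below, those chosen only after the result was seen were the tests of heterozygous replicate 3, of 2 active X chromosomes, and of the escape genes without Jpx and Ftx. The higher let-7 targets were set against 3 technical explanations. Their median lay above all 10000 random lists of the same size matched on mean expression (percentile 100; highest random median 0.29), which argues against expression level. With the proliferation median as a covariate and shared members removed, the median was 0.66. The bootstrap interval of that median, 0.27 to 0.89, resamples the listed genes and not the arrays. This argues against the low proliferation level of heterozygous replicate 3 (-1.08) as the whole cause. Among the other arrays the covariate ran with the genotype (heterozygous 0.03 and 0.00, null 0.22, 0.61 and 0.17). The check cannot separate that part of proliferation from the genotype. Without probe sets of the s or x suffix the median was 0.53 (0.30 to 0.83, by the same bootstrap). Only E2f5, Igf2bp3, Pbx3, Limd2 and Rrm2 of the tested members were represented by such probe sets, too few to move the median far. That check therefore cannot decide on cross-hybridising probe sets. A hypothesis that these values leave open is that loss of let-7 in the null cells raised the level of its targets, but no microRNA was measured here, the lines may differ in other ways, and camera with an estimated correlation did not pass.

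The higher proliferation genes may in part reflect 1 array. Without heterozygous replicate 3 the median difference went from 0.76 to 0.38, a ratio of 0.50. A bootstrap over the list's genes, not over arrays, gave an interval of 0.38 to 0.66, which spans the bound set for the test. These genes move together (estimated correlation 0.727), so that interval is likely too narrow. The list kept its camera call then (limma adjusted p = 2.89e-05), but with all arrays it did not pass with an estimated correlation (0.907) or with fry (0.319). How much of the difference belongs to that array and how much to the genotype stays open. Cells were harvested at confluence, and a difference in density at harvest was not tested.

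Xist lay at background in null replicate 3, in all 3 of its probe sets. Null replicate 1, part of the reference used below, also lay under every heterozygous array in each of them (9.82, 7.73 and 9.79). If both X chromosomes were active in null replicate 3, X-linked genes would lie higher. The median of 348 X-linked genes against the other null arrays, relative to autosomal genes, was 0.0525, which argues against this. Its bootstrap interval, 0.01 to 0.09, resamples the genes and not the arrays. Of 7 genes known to escape X inactivation 6 were lower in that array than the mean of the other 2 null arrays and 4 lower than both, with a median of -0.27, at percentile 0.25 among matched random X-linked lists; without Jpx and Ftx, which lie beside Xist, the median of the other 5 was -0.27 (percentile 0.08), with 2 lower than both arrays. These values are consistent with a loss of the inactive X chromosome in that sample, a hypothesis found and tested on 1 array. Copy number was not measured here, and other causes of the low Xist values were not tested.

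The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many changed probe sets (756, highest other 0) and genes (395, highest other 0). Every other split mixes the groups, so a group difference of any cause widens its residual spread and lowers its count. The contrast of these counts therefore adds little. The real split was also the 1 split with as large a median difference for the let-7 (0.47, highest other 0.31), oncofetal (1.77, highest other 0.79) and proliferation lists (0.76, highest other 0.65). For chromosome 8 (0.19, highest other 0.20) and chromosome 6 (0.16, highest other 0.16), 2 of the 10 splits gave as large a value.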
